A study of Arabidopsis thaliana with 12 samples.

How the data were processed

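The series holds 12 Affymetrix ATH1 arrays of Arabidopsis thaliana root tips, 3 for each of 4 groups: Col-0 and ibr1ibr3ibr10, each on DMSO and on 10 µM IBA. Per the labels' protocols, 100 ng of total RNA was spiked with bacterial control transcripts, amplified with a 3' in vitro transcription kit, labelled with biotin and hybridised in 1 colour. Per the labels, the replicates were independent and each pooled at least 120 root tips. The titles of the DMSO samples give 0 h where their source and treatment labels give 6 h on the control medium, and 6 h was used. The titles also shorten the mutant to ibr3 where the genotype labels give the triple mutant, and the triple mutant was used.

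The deposited values are on the log2 scale, from 1.401 to 13.45, and were made with RMA and the R package affy 1.40.0, per the submitters' processing notes. RMA subtracts background, makes the arrays' probe intensities equal in distribution and summarises the probes of a probe set. It therefore sets changes relative to the bulk of the transcripts, and a shift of most transcripts in 1 direction would not show. Which arrays were normalized together is not given in the sources used here. Arrays have no read depth, and the 3 arrays per group limit the precision.

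Of 22810 probe sets, 64 Affymetrix controls were left out of the tests, which left 22746. The platform annotation names 1 gene for 13513 of them, several for 503 and none for 8730; no gene was named from a probe set with several. Symbols were updated through Entrez identifiers to the RefSeq annotation of TAIR10.1, used for names and gene order alone; 77 identifiers were not in it and kept their names. Where a gene had several probe sets, the one with the highest mean over the 12 arrays stood for it, which gave 13356 genes.

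Group means of the 4 groups were fitted over the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 5.62 prior degrees of freedom, no trend). The contrasts were IBA minus DMSO in each genotype, the mutant response minus the Col-0 response, and the mutant minus Col-0 on each medium. p-values were adjusted within a contrast over the tested probe sets (Benjamini-Hochberg), and an adjusted p under 0.05 was called; tests were two-sided. No filter on dim probe sets was applied. No detection calls were used here; raising dim means to 3.24, the 30th percentile of probe set means, was added after the results were seen, and that level is a rank, not a measured background. The share of the Col-0 response left in the mutant was the median ratio of the changes over the probe sets called in Col-0.

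The 22 gene lists held 341 genes, of which 49 had a probe set that names 1 gene. The lists were Aux/IAA repressors, auxin inactivation, auxin transport, auxin perception and ARFs, auxin biosynthesis, lateral root founding and initiation, peroxisomal beta-oxidation and import, mitosis, G1 and S phase, xenobiotic detoxification, ethylene, cytokinin, cell wall loosening, jasmonate and wounding, circadian clock, and markers of root cap, stem cell niche, root hair and epidermis, xylem, phloem, endodermis and green shoot tissue. The 5 lists of auxin perception, ethylene, jasmonate, xylem and phloem had 0 measured genes and were not analysed here. The 7 lists with at least 3 measured genes, a minimum set after the numbers of measured genes were seen, were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists within a contrast), beside the same test with an estimated correlation. 1 list gene whose symbol and locus disagreed was taken by its symbol.

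The groups, contrasts, lists and alternatives were fixed before the data were examined, as was the rule for named genes. That rule took genes with a called probe set and no overlap between the single arrays of both groups (for the difference of responses, a call alone): the 10 largest rises and falls in Col-0, 5 and 5 in the mutant, 8 and 8 for the difference of responses, 8 and 8 between genotypes on DMSO and 5 and 5 on IBA. Up to 4 members per list with the smallest p were named as well, and IBR1, IBR3 and IBR10, which have no named probe set here and were not analysed here.

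The alternatives were a replicate block, median centring, quantile normalization, a filter on the dimmest 30% of probe sets, a fit of the compared groups alone, eBayes with trend and robust settings, array weights, 1 probe set per gene, stricter thresholds and leaving out each array in turn. Scaling each array to the mean of its 24 poly-A control probe sets was added after these were seen to differ, and a replicate block within each medium after same-numbered arrays on 1 medium were seen to deviate alike. The steps were tested on simulated data in which 200 probe sets were changed by known amounts. For the IBA response in Col-0, 76.1% of changes of 0.5 log2 units, 98.5% of changes of 1 and 100% of changes of 2 were recovered, with 12 false calls among 195. For the difference of responses, which has a larger error, 29.9%, 98.5% and 100% were recovered. The simulated noise was independent between probe sets, and far fewer probe sets were changed than were called in Col-0 (5345). These rates therefore test the steps and need not hold for the real comparisons.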

Results

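Transcript levels were measured in root tip segments, about 4 mm long, of Arabidopsis thaliana seedlings harvested 3 days after germination. The seedlings were the wild type Col-0 or the triple mutant ibr1ibr3ibr10, and had spent 6 h on medium with DMSO or with 10 µM indole-3-butyric acid (IBA). IBA is an auxin precursor that is shortened to the active auxin indole-3-acetic acid (IAA) in peroxisomes, and IBR1, IBR3 and IBR10 act in that conversion. Each of the 4 groups held 3 independent biological replicates, and each replicate pooled at least 120 root tips on 1 ATH1 array. The 12 arrays gave log2 expression values between 1.401 and 13.45, with a median of 5.24 over probe set means. Their number limits the precision. No detection calls were used here, so means under 3.24, the 30th percentile of probe set means, are called dim below: they are not shown to be above background, and changes from or to them are also given with the dim means raised to that level. Replicates of 1 group correlated at r = 0.995 to 0.998 across probe sets, which are not independent replicates, and no pair of arrays was identical. The transcripts of IBR1, IBR3 and IBR10 have no named probe set here, so the mutations were not analysed here at the transcript level.

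The first comparison asked which transcripts respond to IBA where it can be converted to IAA. GH3.3, which encodes an enzyme that conjugates IAA to amino acids, rose in Col-0 from a dim 2.62 ± 0.15 on DMSO to 7.93 ± 0.47 on IBA (log2, mean ± SD, n = 3), a change of 5.31 (SE 0.18, adjusted p = 3.97e-10), or 4.69 from the raised level. The GDSL lipase family genes AT1G74460, AT3G50400 and AT2G23540 rose by 4.44 (SE 0.30), 3.92 (SE 0.30) and 3.87 (SE 0.60). The peroxidase family gene AT1G68850 rose by 4.17 (SE 0.37) and XTH26, a xyloglucan endotransglucosylase/hydrolase that acts on cell walls, by 3.04 (SE 0.10). The other rises among the 10 largest were AT4G38080 (4.93), AT5G12420 (3.83), AT2G22510 (3.27) and AT4G36610 (3.06). The largest falls were those of AT5G04120 (-3.25, SE 0.18), XTH16 (-2.38, SE 0.19), AT4G11210 (-2.30, SE 0.09) and AT5G66815 (-2.25, SE 0.10). The remaining 6 of the 10 largest falls lay between -2.21 for AT4G01140 and -1.87 for AT2G40250, and included AT4G25250 (-2.14), AT3G59370 (-2.11), AT1G24735 (-1.99) and AT1G61840 (-1.99).

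Of 9 measured genes that inactivate auxin 5 rose in Col-0 and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 8.27e-07) and 5 and 2 with spike scaling. Beside GH3.3 these were AT1G14120 (DAO2), named after its value was seen to complete the 5, which rose by 2.97 (SE 0.40), WES1 (GH3.5) by 2.33 (SE 0.11), AT1G14130 (DAO1), an IAA oxidase, by 1.55 (SE 0.12) and GH3.1 by 1.31 (SE 0.11). All 4 measured genes of lateral root founding and initiation, from 23 listed, rose, and all 4 did so when adjusted over the list alone (camera adjusted p = 1.17e-05). LBD16, a transcription factor of lateral root initiation, rose by 1.47 (SE 0.10), LBD29 by 1.32 (SE 0.16), PUCHI by 0.92 (SE 0.19) and the receptor kinase gene CR4 (ACR4) by 0.36 (SE 0.09). The 3 measured genes of xenobiotic detoxification also rose, UGT73B5 by 0.86 (SE 0.08), UGT73B4 by 0.84 (SE 0.09) and GSTU25 by 0.63 (SE 0.07), with all 3 passing when adjusted over the list alone (camera adjusted p = 1.12e-05). These 3 list calls held with an estimated correlation (adjusted p = 0.00398, 0.00588 and 0.0143). With spike scaling the calls of CR4 (-0.08) and GSTU25 (0.19) ended.

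Of 7 measured Aux/IAA genes, which encode repressors of auxin response, 3 rose in Col-0 and 0 fell, with the same counts when adjusted over the list alone: IAA29 by 0.82 (SE 0.11), IAA18 by 0.58 (SE 0.12) and IAA30 by 0.47 (SE 0.12). As a set these 7 genes, of 29 listed, did not pass (camera adjusted p = 0.106), but did without Col-0 IBA replicate 1 (adjusted p = 0.0416, and 0.0416 to 0.233 over 10 alternatives). The other listed Aux/IAA genes have no probe set that names 1 gene here, so the result does not cover the family. Among 5 cell wall loosening genes EXPA4 rose by 0.69 (SE 0.10), 0 fell, and adjusted over the list alone 2 rose. The list call (camera adjusted p = 0.04) was lost in the version of the test with an estimated correlation (adjusted p = 0.0913). The estimate was 0.00935, under the preset 0.01, so a higher correlation is not why the call was lost. The list call was also lost with eBayes trend and robust settings (adjusted p = 0.0736), without the dimmest 30% of probe sets (0.107) and without Col-0 DMSO replicate 1 or 2 or Col-0 IBA replicate 2 (0.0587 to 0.0917, and 0.0264 to 0.107 over 10 alternatives). Both lists flip direction when the arrays are scaled to spiked bacterial transcripts, with medians of -0.31 for Aux/IAA and -0.16 for cell wall loosening. Of 4 auxin biosynthesis genes 0 rose and 1 fell by both adjustments, YUC6 by 0.35 (SE 0.10), and the list did not pass (adjusted p = 0.296), while all 4 fell with spike scaling (median -0.60 instead of -0.16). Of 3 measured genes of peroxisomal beta-oxidation and import, from 24 listed, AIM1 rose by 0.38 (SE 0.08), or 2 adjusted over the list alone. That list did not pass (adjusted p = 0.106) and its median flips to -0.06 with spike scaling. WAG2, a kinase gene of auxin transport, rose by 0.84 (SE 0.12) and RR16 (ARR16), a cytokinin response regulator, by 0.94 (SE 0.13).

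**Figure D1:**
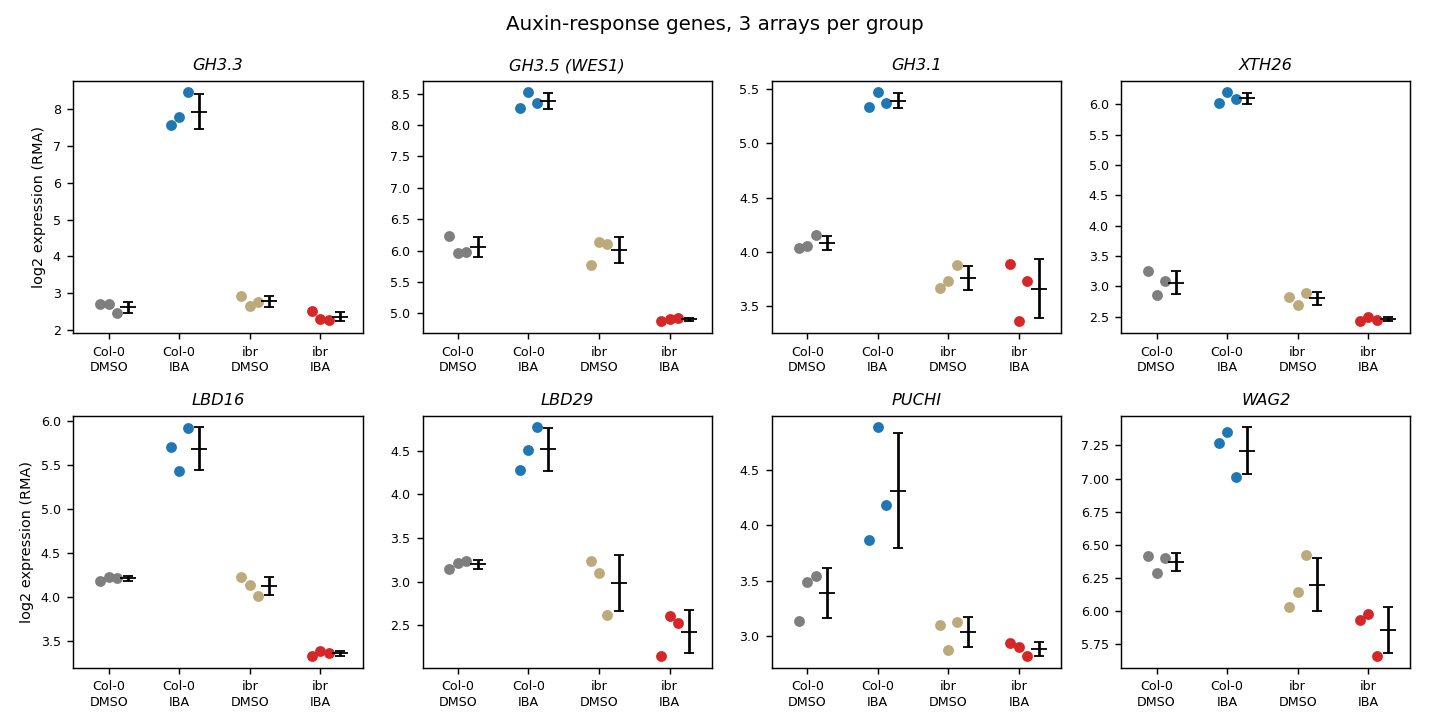
Log2 expression of 8 auxin-response genes on each array (points, coloured by group) with the mean and SD of the 3 arrays of each group (bars); each panel has its own vertical axis, and ibr marks the ibr1ibr3ibr10 mutant. GH3.3 lies at 7.93 on IBA in Col-0 and at 2.36 on IBA in the mutant, and each of the other 7 genes is also highest in Col-0 on IBA.

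In all, 2758 of 22746 tested probe sets rose in Col-0 and 2587 fell (limma, adjusted p under 0.05), 23.5% of those tested. Of these, 471 rose and 127 fell by at least 1 log2 unit. Of 42 named calls 10 have a dim mean, so their size and order are uncertain: beside GH3.3, the changes with it raised are 4.89 for AT4G38080, 3.755 for AT1G68850, 3.64 for AT2G23540, 2.86 for XTH26, 2.63 for AT2G22510, 1.27 for LBD29, 0.74 for IAA29, 0.51 for RR16 and -1.11 for AT2G40250. The changes are relative to the arrays' common scale: 51.6% of calls were higher as deposited, 34.7% after centring each array on its median (2311 and 4356) and 4.25% after scaling to the spiked transcripts (723 and 16287), which moved the median of all probe sets from -0.04 to -0.48. Spike scaling ended the calls of IAA29 (0.38, SE 0.18), IAA18 (0.14), IAA30 (0.03), CR4 (-0.08), AIM1 (-0.06), GSTU25 (0.19) and EXPA4 (0.25), with smaller changes and a median SE of 0.169 against 0.102. The YUC6 call was lost without Col-0 DMSO replicate 1 or 2 or Col-0 IBA replicate 1 (adjusted p up to 0.0746).

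The mutant comparison asked what response to IBA is left without IBR1, IBR3 and IBR10. The formate dehydrogenase gene FDH rose by 1.98 (SE 0.15) in ibr1ibr3ibr10, and AT1G68620, AT1G60750, AT2G41810 and AT3G61390 rose by 2.18 (SE 0.22), 2.16 (SE 0.15), 2.13 (SE 0.34) and 1.94 (SE 0.16). AT1G34510, a peroxidase family gene, fell from 6.02 ± 0.20 on DMSO to 3.42 ± 0.42 on IBA (n = 3), a change of -2.61 (SE 0.18, adjusted p = 2.94e-06). The next largest falls were those of AT1G34330 (-2.11, SE 0.13), AT4G25790 (-1.67, SE 0.14), AT5G04120 (-1.37, SE 0.18) and AT1G33700 (-1.32, SE 0.10). GH3.3 was at 2.78 ± 0.14 on DMSO and 2.36 ± 0.13 on IBA (n = 3), a difference that did not pass.

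Auxin inactivation genes went both ways in the mutant, with 2 of 9 rising and 2 falling, and the same counts when adjusted over the list alone (camera adjusted p = 0.784), or 1 and 1 with spike scaling, where the median flips from -0.03 to 0.07. WES1 fell by 1.11 (SE 0.11) and GH3.17 by 0.45 (SE 0.08), while AT1G14130 rose by 1.07 (SE 0.12) and UGT74D1, a glucosyltransferase gene, by 0.26 (SE 0.07). Of 4 lateral root genes 2 were called lower, and the same 2 when adjusted over the list alone: LBD16 fell by 0.77 (SE 0.10), while LBD29 was dim in both groups (2.98 ± 0.33 and 2.43 ± 0.25, n = 3), so its change has no size here; PUCHI was at -0.15 (SE 0.19) and CR4 at -0.06 (SE 0.09). The call of that list (camera adjusted p = 0.0292) was lost in the version of the test with an estimated correlation (adjusted p = 0.0982), without the dimmest 30% of probe sets (0.112) and without mutant DMSO replicate 1 (adjusted p = 0.0733, and 0.0111 to 0.112 over 10 alternatives). The estimated correlation was -0.0861, under the preset 0.01, so a higher correlation is not why that version lost the call. All 3 xenobiotic detoxification genes rose, UGT73B5 by 0.69 (SE 0.08), UGT73B4 by 0.62 (SE 0.09) and GSTU25 by 0.56 (SE 0.07), with the same count when adjusted over the list alone (adjusted p = 1.05e-06, and 0.0221 with an estimated correlation). Of the root hair markers EXPA18 fell by 0.60 (SE 0.09) and EXPA7 by 0.26 (SE 0.07). Of 5 cell wall loosening genes XTH19 fell by 0.48 (SE 0.09) and EXPA4 by 0.40 (SE 0.10), or 3 of 5 adjusted over the list alone. The cell wall list did not pass (adjusted p = 0.0501), but did with eBayes trend and robust settings (adjusted p = 0.0278) and without mutant DMSO replicate 2 or 3 or mutant IBA replicate 2 or 3 (between 0.0215 and 0.0419; up to 0.176 over 10 alternatives). IAA31 was the 1 of 7 Aux/IAA genes to fall, by 0.71 (SE 0.18; list adjusted p = 0.436), and 0 of 4 auxin biosynthesis genes passed (adjusted p = 0.664). ICL, which encodes isocitrate lyase, was the 1 of 3 peroxisomal genes to rise, by 0.70 (SE 0.20; adjusted p = 0.3). The same counts held for these 3 lists when adjusted over the list alone.

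In the mutant 1248 probe sets rose and 881 fell, 9.36% of those tested. Of 27 named calls 4 have a dim mean: beside LBD29, the changes with it raised are 1.66 for AT3G61390, -1.91 for AT1G34330 and -0.32 for IAA31. The total of 2129 dropped to 1168 without mutant DMSO replicate 2, to 1398 without mutant DMSO replicate 3 and to 1298 without mutant IBA replicate 3. Spike scaling moved the share of higher calls from 58.6% to 84.3% (798 and 149). The calls of UGT74D1, IAA31, LBD29, ICL, EXPA4, EXPA7 and AT1G72140 (NPF5.12) were each lost on leaving out 1 of at least 2 of the 6 arrays in turn (adjusted p between 0.0504 and 0.174). With spike scaling these changes kept their direction and most of their size, but 8 calls ended as the median SE rose from 0.092 to 0.173: UGT74D1 (0.36), LBD29 (-0.46), AT1G72140 (-0.55), GH3.17 (-0.35), XTH19 (-0.39), EXPA4 (-0.31), EXPA18 (-0.50) and EXPA7 (-0.16). With a replicate block LBD29 and EXPA7 did not pass (adjusted p = 0.0635 and 0.0561).

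The difference between both responses was tested directly, as the mutant response minus the Col-0 response. GH3.3, dim in all groups but Col-0 on IBA, had the most negative difference, -5.72 (SE 0.25, adjusted p = 1.5e-08) or -4.69 with dim means raised, followed by AT1G34510 (-3.76, SE 0.25), AT4G38080 (-3.53, SE 0.58), WES1 (-3.43, SE 0.15) and XTH26 (-3.38, SE 0.14). The GDSL lipase genes AT2G23540 and AT1G74460 and the peroxidase gene AT1G68850 came next at -3.18 (SE 0.85), -3.15 (SE 0.42) and -2.76 (SE 0.52). On DMSO AT4G38080, AT2G23540 and AT1G68850 were already higher in the mutant, by 3.22, 3.46 and 2.32, as was AT1G74460. A difference of responses is the genotype difference on IBA minus that on DMSO. For AT2G23540 the higher level on DMSO (3.46) exceeds the size of its difference of responses (-3.18), so no lower mean on IBA enters it. For AT4G38080, AT1G68850 and AT1G74460 the higher level on DMSO makes up most of the difference of responses, and a lower level on IBA a smaller part. The most positive differences were those of AT1G62510 (2.89, SE 0.18), AT1G14550 (2.41, SE 0.24), AT4G01140 (2.28, SE 0.17) and AT2G40250 (2.27, SE 0.21). AT1G62510 fell by 1.38 in Col-0 and rose by 1.51 in the mutant, and AT4G01140, which fell by 2.21 in Col-0, was at 0.07 in the mutant.

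The response was lower in the mutant for 5 of 9 auxin inactivation genes (6 adjusted over the list alone; camera adjusted p = 7.78e-08) and 3 of 4 lateral root genes (4 adjusted over the list alone; 4.48e-08), and higher for 0 in both. With spike scaling the first list had 3 genes higher and 4 lower (median -0.06 instead of -0.60) and the second 0 higher and 2 lower. LBD16 differed by -2.24 (SE 0.15), LBD29 by -1.88 (SE 0.23), GH3.1 by -1.41 (SE 0.16) and GH3.17 by -0.60 (SE 0.11). Of 5 cell wall loosening genes 2 were lower (3 adjusted over the list alone; 0.000555), EXPA4 by -1.09 (SE 0.15) and XTH19 by -0.60 (SE 0.13). Of 7 Aux/IAA genes 1 was lower, IAA29 by -0.99 (SE 0.15), or 2 adjusted over the list alone (0.0144). With spike scaling 1 cell wall loosening gene was higher and 0 lower (median -0.05 instead of -0.59). These 4 list calls held with an estimated correlation (adjusted p = 0.00139, 0.00139, 0.0145 and 0.0458), although the Aux/IAA median flips from -0.30 to 0.24 under spike scaling. Both measured auxin transport genes were lower, WAG2 by -1.18 (SE 0.17) and AT1G72140 by -0.996 (SE 0.21), as was RR16 by -1.01 (SE 0.18). For xenobiotic detoxification 0 of 3 genes passed (list adjusted p = 0.145), with differences of -0.22 (SE 0.12) for UGT73B4, -0.17 (SE 0.11) for UGT73B5 and -0.07 (SE 0.09) for GSTU25. The median of that list flips from -0.17 to 0.37 under spike scaling. Auxin biosynthesis (0 of 4, adjusted p = 0.145) and the peroxisomal genes (0 of 3, adjusted p = 0.486) did not pass, also when adjusted over the list alone, but with spike scaling 4 of 4 (median 0.74 instead of 0.21) and 2 of 3 (0.585 instead of 0.05) were higher in the mutant.

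**Figure D2:**
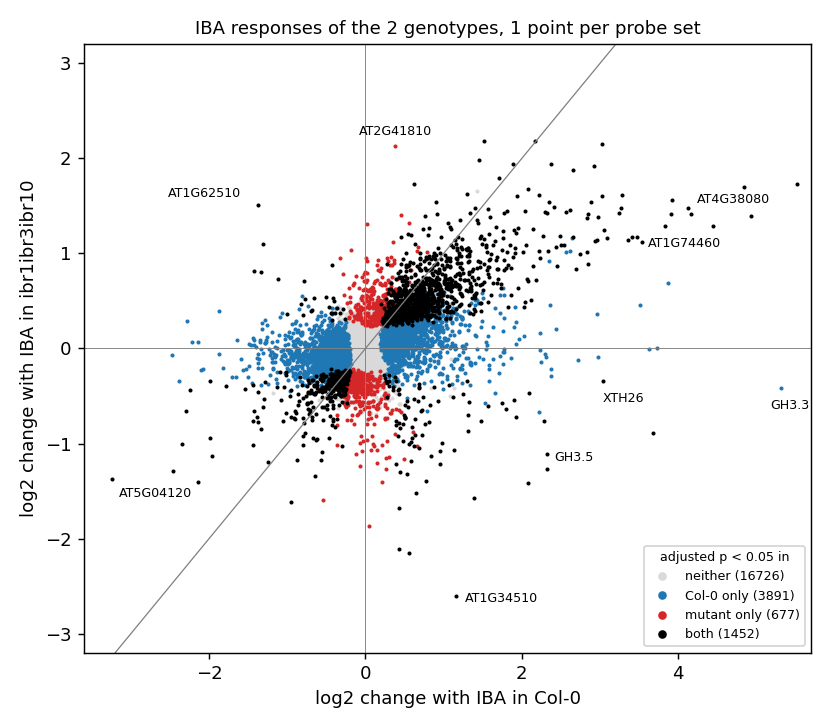
Log2 change with IBA in Col-0 (horizontal axis) against that in ibr1ibr3ibr10 (vertical axis), 1 point per probe set; colours mark adjusted p under 0.05 in Col-0 alone (3891), the mutant alone (677), both (1452) or neither (16726), and the diagonal marks equal change. GH3.3 lies at 5.31 in Col-0 and -0.41 in the mutant, and AT1G34510 at 1.16 and -2.61.

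The 2 responses differed for 1478 probe sets, higher in the mutant for 672 and lower for 806. Of 29 named calls 10 have a dim mean: beside GH3.3, the differences with it raised are -3.495 for AT4G38080, -2.95 for AT2G23540, -2.86 for XTH26, -2.34 for AT1G68850, -1.27 for LBD29, -0.92 for PUCHI, -0.74 for IAA29, -0.51 for RR16 and 1.5 for AT2G40250. Of the 2758 that rose in Col-0, 959 also rose in the mutant (151.3 expected from independent lists), 87 fell (106.8 expected) and 1712 were not called, and the difference opposed the Col-0 change in 703. Of the 2587 that fell in Col-0, 380 also fell in the mutant (100.2 expected) and 26 rose (141.9 expected). Over all probe sets the changes correlated at r = 0.50 and rho = 0.39, across probe sets that are not independent, and the comparisons share no array. The mutant change was 0.42 of the Col-0 change at the median of risers (SD 0.02 over the 3 mutant IBA arrays, with the other arrays held fixed) and 0.31 of it for those that fell (SD 0.05). The probe sets were chosen on the same Col-0 arrays; with calls from 2 Col-0 replicates and the change from the remaining one, the ratio was 0.56, 0.45 or 0.38 for risers and 0.287, 0.301 or 0.215 for those that fell. Among those that fell by at least 1 log2 unit it was 0.105. The ratio was not computed with spike scaling, which adds -0.441 to every Col-0 change and 0.097 to every mutant change. Median changes in Col-0 and the mutant were 0.54 and 0.24 for risers, and -0.37 and -0.12 for those that fell. Beside these the shifts are large, so the ratio holds for the deposited scale alone. Of the risers, 373 were already called higher in the mutant on DMSO. Over these the median change was 1.04 in Col-0 and 0.53 in the mutant, with a median genotype difference on IBA of 0.07. A low ratio can thus come with a higher level on DMSO, without a lower level on IBA. After median centring 57.1% of the differing probe sets were higher in the mutant instead of 45.5%, and after spike scaling 98% (11637 and 237, with the median of all probe sets at 0.55). The AT2G23540 and PUCHI calls were lost on leaving out any of 9 and any of 6 of the 12 arrays (adjusted p up to 0.111 and 0.0704). The AT2G23540 call was also lost with a replicate block (adjusted p = 0.0773). Spike scaling ended those of IAA29 (-0.45), GH3.17 (-0.06), AT1G72140 (-0.46), PUCHI (-0.53), RR16 (-0.47), EXPA4 (-0.55), XTH19 (-0.06) and EXPA18 (-0.31), with smaller differences and a median SE of 0.248 against 0.149.

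The genotypes were next compared on DMSO, without added IBA. AT3G55920, a cyclophilin family gene, was at a dim 2.84 ± 0.17 in Col-0 and 7.67 ± 0.05 in the mutant (n = 3), a difference of 4.83 (SE 0.09, adjusted p = 4.33e-13), or 4.42 from the raised level. The GDSL lipase genes AT2G23540, AT1G74460 and AT3G50400 were higher in the mutant by 3.46 (SE 0.60), 2.47 (SE 0.30) and 2.07 (SE 0.30), and AT4G38080, AT5G09570, AT5G12420 and AT1G68850 by 3.22 (SE 0.41), 2.42 (SE 0.16), 2.34 (SE 0.22) and 2.32 (SE 0.37). QQS, a gene linked to starch content, differed by -2.57 (SE 0.17), from 5.26 ± 0.39 to 2.70 ± 0.22 (n = 3). The next most negative differences were those of AT5G24340 (-1.57, SE 0.11), AT4G14270 (-1.22, SE 0.11) and AT1G65370 (-1.16, SE 0.14), followed by AT3G47080 (-0.99), AT5G49870 (-0.98), AT5G62330 (-0.95) and AT5G04120 (-0.93).

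On DMSO the lists of auxin response did not pass: 0 of 4 lateral root genes (adjusted p = 0.792) and 0 of 7 Aux/IAA genes (0.802) were called, also when adjusted over the list alone. Of 9 auxin inactivation genes AT1G14130 was higher by 0.53 (SE 0.12, list adjusted p = 0.411), and adjusted over the list alone 2 were higher and 1 lower. AT1G14120 was at 1.61 (SE 0.40) and did not pass by limma (adjusted p = 0.0537). It did pass with spike scaling (adjusted p = 4.21e-05) and with a replicate block within each medium (0.0074). Xenobiotic detoxification was higher in the mutant (adjusted p = 1.6e-06, and 0.0241 with an estimated correlation), with 2 of 3 genes passing and 3 adjusted over the list alone: UGT73B4 by 0.55 (SE 0.09) and GSTU25 by 0.40 (SE 0.07), with UGT73B5 at 0.30 (SE 0.08). EXPA18 was lower by -0.46 (SE 0.09), and RR16 was called lower but dim in both genotypes (2.82 ± 0.24 and 2.15 ± 0.14, n = 3). Cell wall loosening (0 of 5, or 2 higher adjusted over the list alone; 0.411), auxin biosynthesis (0 of 4; 0.907) and the peroxisomal list (0 of 3, or 1 adjusted over the list alone; 0.0832) did not pass. The peroxisomal list did pass without Col-0 DMSO replicate 2 or mutant DMSO replicate 3 (adjusted p = 0.0282 and 0.0162; up to 0.218 over 10 alternatives).

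**Figure D3:**
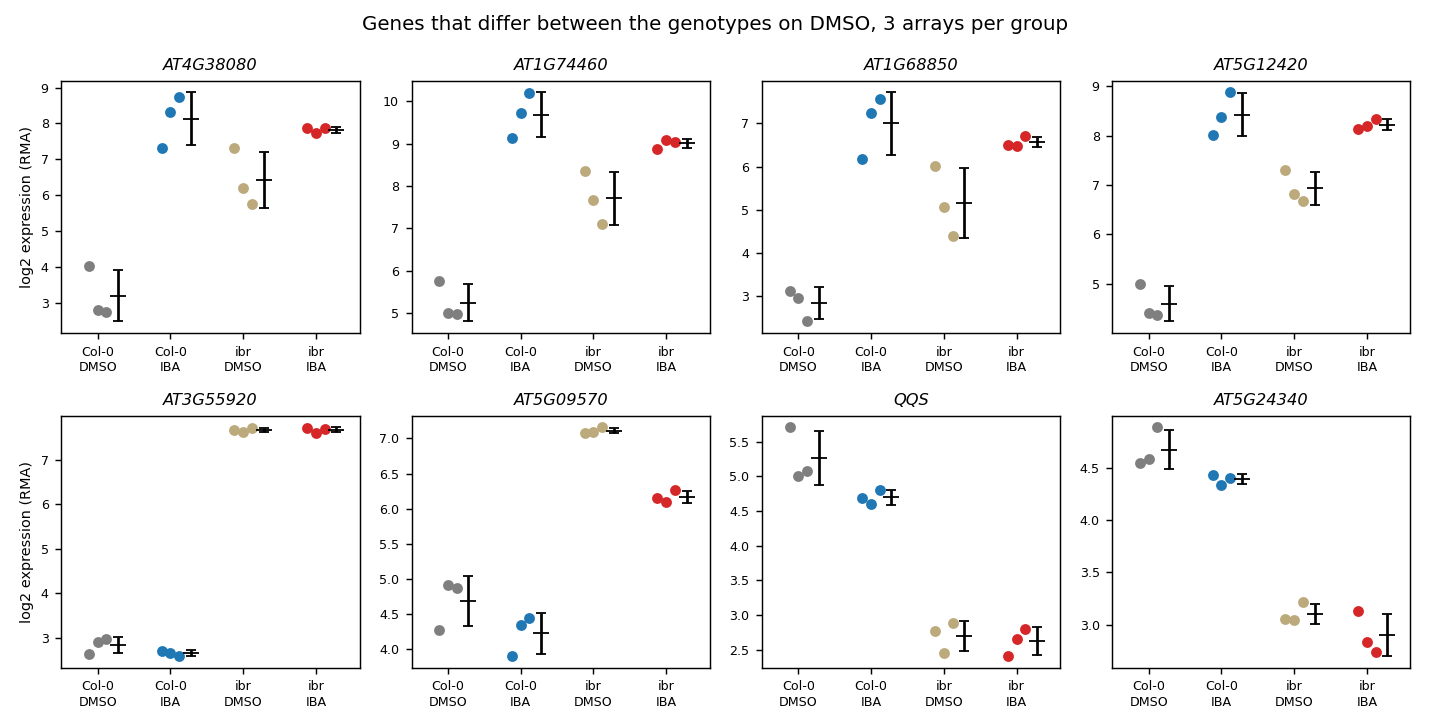
Log2 expression of 8 genes that differ between the genotypes on DMSO, on each array (points, coloured by group), with the mean and SD of the 3 arrays of each group (bars); each panel has its own vertical axis, and ibr marks the ibr1ibr3ibr10 mutant. The 4 genes of the upper panels, such as AT1G74460 at 5.24 in Col-0 on DMSO and 7.71 in the mutant, are high in both genotypes on IBA, while AT3G55920 is at 2.65 in Col-0 and 7.67 in the mutant on IBA.

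On DMSO 413 probe sets were higher in the mutant and 137 lower, 2.42% of those tested. Of 22 named calls 7 have a dim mean: beside AT3G55920 and RR16, the differences with it raised are 3.22 for AT2G23540, 3.18 for AT4G38080, 1.91 for AT1G68850, -2.02 for QQS and -1.43 for AT5G24340. The total of 550 dropped to 277 without mutant DMSO replicate 1, 298 without Col-0 DMSO replicate 3, 357 without Col-0 DMSO replicate 2 and 363 without mutant DMSO replicate 2. The share of higher calls was 75.1%, against 64.2% after median centring (335 and 187) and 55.1% after spike scaling (114 and 93, with the median of all probe sets at -0.15). The calls of AT1G14130, EXPA18, RR16 (without mutant DMSO replicate 1) and AT5G04120 (without Col-0 DMSO replicate 3) were lost without single arrays, with adjusted p between 0.0505 and 0.113. With spike scaling the differences of UGT73B4 (0.41), GSTU25 (0.27), AT1G14130 (0.397), RCA (0.49) and EXPA18 (-0.597) kept their direction, but their calls ended as the median SE rose from 0.090 to 0.174.

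On IBA the genotypes differed more widely. GH3.3 differed most, with the mutant lower by -5.57 (SE 0.18, adjusted p = 1.05e-10), AT1G34510 by -4.46 (SE 0.18), XTH26 by -3.64 (SE 0.10), WES1 by -3.48 (SE 0.11) and AT1G34330 by -3.08 (SE 0.13). AT3G55920 was higher by 5.02 (SE 0.09), close to its difference on DMSO, followed by AT1G62510 (3.03, SE 0.13), AT2G40250 (2.69, SE 0.15), AT1G14550 (2.48, SE 0.17) and AT2G41810 (2.40, SE 0.34). The cytokinin response regulators RR16 and ARR15 were lower, by -1.68 (SE 0.13) and -1.23 (SE 0.21), and the auxin transport genes WAG2 and AT1G72140 by -1.35 (SE 0.12) and -1.25 (SE 0.15).

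Of the auxin inactivation list 4 of 9 genes were lower on IBA (adjusted p = 1.65e-05; adjusted over the list alone 5 lower and 1 higher; 4 higher and 4 lower with spike scaling, median -0.16 instead of -0.56), GH3.1 by -1.73 (SE 0.11) and GH3.17 by -0.56 (SE 0.08). Lateral root genes were lower in 3 of 4 (2.79e-08; 4 adjusted over the list alone), LBD16 by -2.33 (SE 0.10), LBD29 by -2.09 (SE 0.16) and PUCHI by -1.42 (SE 0.19). The Aux/IAA list was lower in 3 of 7 (0.00933; 3 adjusted over the list alone), IAA31 by -1.23 (SE 0.18), IAA29 by -1.08 (SE 0.11) and IAA30 by -0.61 (SE 0.12), although its median flips from -0.29 to 0.11 under spike scaling. Cell wall loosening was lower in 3 of 5 (0.00203; 3 adjusted over the list alone), EXPA4 by -0.81 (SE 0.10), XTH19 by -0.79 (SE 0.09) and EXPB3 by -0.43 (SE 0.12), against 1 higher and 2 lower with spike scaling (median -0.03). These 4 calls held with an estimated correlation (adjusted p = 0.005, 0.00232, 0.0402 and 0.0241). Xenobiotic detoxification was higher in 2 of 3 genes, also adjusted over the list alone (0.00933), GSTU25 by 0.33 (SE 0.07) and UGT73B4 by 0.32 (SE 0.09). This list call was lost with an estimated correlation (adjusted p = 0.0895 with an estimated correlation). With spike scaling UGT73B5 was called higher as well (0.54 instead of 0.13), and UGT73B4 was at 0.73. Auxin biosynthesis (YUC6 higher by 0.46, SE 0.10, or 2 of 4 adjusted over the list alone; 0.135) and the peroxisomal list (ICL higher by 0.88, SE 0.20, 1 of 3 by both adjustments; 0.486) did not pass, with 3 of 4 and 2 of 3 genes higher under spike scaling. Auxin biosynthesis did pass without the dimmest 30% of probe sets (adjusted p = 0.0392; 0.0392 to 0.32 over 10 alternatives).

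On IBA 1353 probe sets were higher in the mutant and 1155 lower, 11% of those tested. Of 33 named calls 11 have a dim mean, and with it raised the differences are -4.69 for GH3.3, -2.88 for AT1G34330, -2.86 for XTH26, -1.27 for LBD29, -1.07 for PUCHI, -0.84 for IAA31, -0.74 for IAA29, -0.51 for RR16, -0.505 for IAA30, 1.92 for AT2G40250 and 4.43 for AT3G55920. After spike scaling 97.4% were higher (13030 and 342) instead of 53.9%, and the median of all probe sets moved to 0.41. The calls of UGT73B4, EXPB3, EXPA7 and GSO1 were each lost without any of at least 3 of the 6 arrays in turn (adjusted p between 0.0598 and 0.136). Spike scaling ended those of IAA30 (-0.20), GH3.17 (-0.16), EXPB3 (-0.03) and EXPA7 (0.13), with smaller differences and a median SE of 0.169 against 0.099.

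The platform annotation names few markers of single root cell types. The root cap polygalacturonase gene AT1G65570 changed by -1.003 (SE 0.14) in Col-0 on IBA and was at -0.12 (SE 0.14) in the mutant, a difference between responses of 0.88 (SE 0.20, adjusted p = 0.0137). GSO1 (SGN3), a receptor of the endodermis, fell by 0.33 (SE 0.09) in Col-0, a call lost without Col-0 DMSO replicate 3 (adjusted p = 0.0539). RCA, the Rubisco activase gene of green tissue, rose by 1.08 (SE 0.11) in Col-0 and 0.63 (SE 0.11) in the mutant on IBA, and was higher in the mutant on DMSO by 0.63 (SE 0.11), or 0.49 (SE 0.17, adjusted p = 0.265) with spike scaling. The mitotic kinase gene AUR2 fell by 0.29 (SE 0.09) in Col-0, a call lost without Col-0 DMSO replicate 2 or 3 or Col-0 IBA replicate 1 (adjusted p up to 0.0928). It was at -0.26 (SE 0.09) in the mutant, where it did not pass, while AUR1 was at -0.17 (SE 0.07) and -0.14 (SE 0.07). The DNA replication gene PRL (MCM7) was at -0.10 (SE 0.07) and -0.11 (SE 0.07), and the stem cell niche marker BBM at 0.05 (SE 0.10) and -0.28 (SE 0.10). The clock gene GI was at -0.06 (SE 0.10) and 0.30 (SE 0.10), and none of these 3 genes passed.

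The spiked bacterial poly-A transcripts, added to each RNA sample, were 0.44 log2 units higher on average in Col-0 on IBA than on DMSO over 24 probe sets, of which 13 were higher and 0 lower. Their means were 4.82 ± 0.08 in Col-0 on DMSO, 5.26 ± 0.28 in Col-0 on IBA, 4.95 ± 0.12 in the mutant on DMSO and 4.86 ± 0.08 in the mutant on IBA (n = 3 each). Col-0 IBA replicates 1, 2 and 3 lay at 5.31, 5.51 and 4.96, against 4.76 to 4.91 in Col-0 on DMSO. The rise thus came mostly from replicates 1 and 2, and spike-scaled results that involve Col-0 on IBA rest largely on these 2 arrays. The hybridisation controls differed by -0.08 in Col-0 and 0.26 in the mutant on IBA, with 0 of 18 called by limma in each, and lay at 8.58 on mutant IBA replicate 1 against 7.74 to 8.09 on the other arrays. The 3' minus 5' difference of the actin control, a measure of RNA integrity and labelling, was 1.695 ± 0.04 in Col-0 on DMSO and 1.95 ± 0.13 on IBA, and 1.81 ± 0.10 and 1.87 ± 0.02 in the mutant. That of the GAPDH control was 0.09 ± 0.02 in Col-0 on DMSO and 0.19 ± 0.16 on IBA, and 0.23 ± 0.11 and 0.08 ± 0.09 in the mutant, where it moved the other way.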

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

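The tests of a higher starting level, of a lower auxin response (both gene sets), of linkage, of genome stretches, of permuted residuals and of replicate order below were chosen after the results were seen, as were spike scaling and the level under which a mean counts as dim. The linkage test was put in its present form after its p had been seen, and a test on 3 genes of dividing cells was dropped after its result had been seen.

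The responses to IBA differ between the genotypes by a direct test for 1478 probe sets. The named genes with a lower response in the mutant (mutant minus Col-0, log2) are GH3.3 (-5.722), AT1G34510 (-3.762), AT4G38080 (-3.533), WES1 (-3.43), XTH26 (-3.378), AT2G23540 (-3.182), AT1G74460 (-3.149) and AT1G68850 (-2.755). Of these, AT4G38080, AT2G23540, AT1G74460 and AT1G68850 were already higher in the mutant on DMSO, which their differences include. Those with a higher response are AT1G62510 (2.89), AT1G14550 (2.409), AT4G01140 (2.284), AT2G40250 (2.266), AT4G25250 (2.205), AT1G49030 (2.145), XTH16 (2.033) and AT3G59370 (1.884). Among list members the differences are -2.238 for LBD16, -1.877 for LBD29, -1.073 for PUCHI, -1.408 for GH3.1, -0.597 for GH3.17, -0.988 for IAA29, -1.182 for WAG2, -0.996 for AT1G72140, -1.005 for RR16, -1.09 for EXPA4, -0.597 for XTH19, -0.852 for EXPA18 and 0.881 for AT1G65570. Spike scaling ended 8 of these calls: PUCHI, GH3.17, IAA29, AT1G72140, RR16, EXPA4, XTH19 and EXPA18. The PUCHI and AT2G23540 calls were also lost on leaving out any of 6 and any of 9 of the 12 arrays. The measured genes differ as sets for the lists of Aux/IAA repressors (7 of 29 listed, camera adjusted p = 0.0144), auxin inactivation (9 of 13, 7.78e-08), lateral root initiation (4 of 23, 4.48e-08) and cell wall loosening (5 of 13, 0.000555). The first list flips direction with spike scaling. The others then have 3 genes higher and 4 lower, 0 and 2, and 1 and 0 (for cell wall loosening against 0 and 2, with a median of -0.053 instead of -0.591). Of the 29 named differences 10 include a mean too dim to be shown above background. Of 100 regroupings of the genotype labels within each medium, drawn from 200, 2 gave as many probe sets, the real one and one with 2180 that swaps the genotypes whole in 1 medium. The rest, 1135 at most, mix the genotypes within groups, which widens the residual spread and holds the count down with or without a difference of responses, so they exclude nothing. With residuals of a model without that difference permuted over the arrays, 1 of 100 draws gave as many, the real one, and the highest of the others gave 2, so chance can be excluded at 0.05 from that test.

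The 4 comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05, and in each 1 of the 10, the real one, gave as many probe sets. The real values are 5345 (IBA in Col-0), 2129 (IBA in the mutant), 550 (genotypes on DMSO) and 2508 (genotypes on IBA), and the highest of the other splits is 0 in each. The other splits mix both groups, which widens the residual spread and holds their counts down, so this 0 excludes nothing.

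The spiked poly-A control probe sets, which no comparison of the study's transcripts uses, are 0.441 higher in Col-0 on IBA than on DMSO. A scaling of the arrays that moves all controls alike is argued against by the hybridisation controls. In Col-0 these were at 7.96 ± 0.12 on DMSO and 7.88 ± 0.06 on IBA (n = 3), with 0 of 18 called. Whether the amount added or the amount of plant RNA differed was not tested.

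The first pattern is a set of 87 probe sets, 44 named genes, that rose with IBA in Col-0 and fell in the mutant, where 106.8 are expected from independent lists, with median changes of 0.63 and -0.72; WES1 (2.33 and -1.11) and AT1G34510 (1.16 and -2.61) are examples. A higher starting level in the mutant is argued against, because the median difference on DMSO is -0.254, not above 0. Array scaling may account for part of the rise in Col-0: 77 of the 87 pass both tests after median centring and 78 after quantile normalization, but 16 after spike scaling, where 30 still rise in Col-0, 48 still fall in the mutant and 64 keep opposite signs. These calls ended because the median rise in Col-0 dropped to 0.19 and the median SE grew from 0.107 to 0.171. The median change in the mutant moved from -0.72 to -0.62, a step fixed by the scaling, which adds 0.097 to every mutant change. By the rule set before this test, that most pass both tests under every scaling, array scaling is not excluded. That rule includes spike scaling, which was added after the spiked transcripts were seen to differ, and spike scaling alone decides this outcome. The fall in the mutant was still called for 87 after median centring and 85 after quantile normalization. A lower auxin response in the mutant on IBA, as a biological explanation, stays open, since the tests run do not decide it: over 20 pooled auxin genes 5 fell and 2 rose (p = 0.0659 by camera, and 0.0091 in a permutation test that takes genes as independent), and over the 17 outside the pattern 2 fell and 2 rose (camera p = 0.802, permutation test p = 0.293).

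The second pattern is a set of 373 probe sets, 176 named genes such as AT1G74460, that are higher in the mutant on DMSO and rose with IBA in Col-0, where 50.08 are expected from independent lists. Both changes are measured against the same Col-0 DMSO arrays. Over all probe sets their covariance is 0.0446, where simulations of shared arrays alone gave 0.00565 on average and 0.00588 at most. The correlation is closer, at 0.59 against 0.5 on average and 0.514 at most, as is the share of equal signs (71.5% against 66.7% and 67.4%). The simulations drew noise independently for each probe set, while these genes deviate together, so their ranges may be too narrow. Shared arrays have little support as the whole cause, but a part is not excluded. Root segment makeup varying between samples may contribute, since these genes deviate together within groups (mean correlation 0.345, against a median of 0.032 and a highest value of 0.0674 over 1000 random lists, and 0.0626 for 1127 other genes that rose). The random lists matched mean expression alone, so genes that are regulated together could deviate alike too, and the test does not tell these apart. Their mean deviations also follow the same order of replicate numbers in both genotypes, from 0.09 (Col-0) and 0.13 (mutant) in replicate 1 to -0.05 and -0.09 in replicate 3 on DMSO, and from -0.16 and -0.04 to 0.17 and 0.04 on IBA. A condition shared by number is balanced, as each group holds each number once. The set's means were 6.14 ± 0.08 in Col-0 and 6.85 ± 0.12 in the mutant on DMSO, and 7.34 ± 0.16 in Col-0 on IBA (n = 3). Such a condition is therefore argued against as the source of the genotype difference on DMSO, and the deviations are small beside the rise with IBA. Correlated deviations do not name the tissue that varies; RCA, the 1 measured marker of green tissue, goes with the set (1.084 with IBA in Col-0 and 0.628 on DMSO), which 1 gene leaves undecided, and an effect of the mutations on these genes, which the design gives as the biological explanation, stays open and was not tested.

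The third pattern is a set of 93 genes that differ between the genotypes the same way on DMSO and on IBA, 43 of them higher in the mutant, such as AT3G55920, and others lower, such as QQS. Linkage within 100 genes of the 3 mutated loci is argued against as the main source, because 2 of 92 placed genes, AT4G05070 and AT4G14270, lie there. Of the measured genes in that window 1.04% differ, against 0.696% of all placed genes (exact hypergeometric test, p = 0.387). Linkage over longer distances was not tested. Stretches of another genome elsewhere cannot be told apart from chance placement: the most in any 50 neighbouring measured genes is 4 (AT3G55890, AT3G55920, AT3G56360 and AT3G56500), against 3 at the median of random lists (permutation p = 0.306). An effect of the mutations themselves stays open and was not tested.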

How the results depend on the processing

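Spike scaling, a replicate block within each medium, the tests of pairing and the level under which a mean counts as dim were chosen after the data were seen. All other alternatives were planned. Over the 5 comparisons, each count stayed within 1.5 times its value with a replicate block, for example 5283 for the IBA response in Col-0 and 472 for the genotype difference on DMSO. Over all groups, deviations of same-numbered arrays correlated at a mean r of 0.010 (exact permutation test, p = 0.338), and 5 of 12 arrays correlated best with their own number, against a median of 4 over renumberings. On the same medium the mean r was 0.077, the highest of 36 renumberings (exact permutation test, p = 0.0278), so samples of 1 medium may share something by number. A block within each medium gave 1494 for the difference of responses, 574 on DMSO and 2476 on IBA, and ended 0 calls of named genes and added 4. The added calls were RCA for the difference of responses (adjusted p = 0.0485), AT1G14120 (0.0074) and ICL (0.0397) on DMSO, and GI on IBA (0.0426). The planned block ended 3 calls: LBD29 and EXPA7 with IBA in the mutant (adjusted p = 0.0635 and 0.0561) and AT2G23540 for the difference of responses (0.0773).

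The counts for IBA in Col-0, IBA in the mutant, the difference of responses, genotypes on DMSO and genotypes on IBA, in this order, were 2720, 997, 734, 248 and 1280 with 1 probe set per gene, because fewer probe sets were tested. They were 3354, 999, 751, 253 and 1535 at an adjusted p under 0.01, and 598, 185, 384, 79 and 369 with an absolute log2 change of at least 1, both stricter by construction. With spike scaling they were 17010, 947, 11874, 207 and 13372. That scaling moves every probe set of a comparison alike, by -0.441, 0.097, 0.538, -0.134 and 0.404, and the errors grow. Why the spiked transcripts themselves differ stays open. Without single arrays they ranged from 4195 to 5179, 1168 to 1829, 1109 to 1620, 277 to 468 and 1862 to 2683, with fewer samples. The lowest for the mutant (1168) came without mutant DMSO replicate 2, with 1398 and 1298 without mutant DMSO replicate 3 and mutant IBA replicate 3. On DMSO, 277, 298, 357 and 363 came without mutant DMSO replicate 1, Col-0 DMSO replicate 3, Col-0 DMSO replicate 2 and mutant DMSO replicate 2.

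The share of the Col-0 response left in the mutant was 0.326 to 0.395 without single arrays, 0.401 to 0.475 for probe sets that rose and 0.219 to 0.33 for those that fell. With the Col-0 change taken from a replicate not used for the calls it was 0.438 (replicate 1) and 0.324 (replicate 3), for risers 0.555, 0.454 and 0.381, and for those that fell 0.215 (replicate 3). It was 0.462 for risers after median centring and 0.105 for those that fell by at least 1 log2 unit; the cause was not tested.

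Under spike scaling the changes of CR4 (-0.080), AIM1 (-0.062) and BBM (-0.393) with IBA in Col-0 and the EXPA7 difference on IBA (0.132) had the opposite sign, because that scaling moves the Col-0 response of every probe set by -0.441 and every difference on IBA by 0.404. Of the single results for named genes, it left 207 of 267 on the same side of the threshold, 28 gained and 32 lost a call, against 262, 4 and 1 with median centring. The median SE of those lost rose from 0.108 to 0.175. The version of the list test with an estimated correlation ended 3 of 16 list calls. For cell wall loosening in Col-0 and lateral root initiation in the mutant the estimates (0.00935 and -0.0861) lay under the preset 0.01. A higher correlation is therefore not why these calls ended. With eBayes trend and robust settings the list of cell wall loosening lost its call in Col-0 (adjusted p = 0.0736; 0.0264 to 0.107 over 10 alternatives) and passed in the mutant (0.0278; 0.0215 to 0.176). Signal over background limits the sizes given: LBD29 in the mutant and RR16 on DMSO lie in both groups under 3.24, the 30th percentile of probe set means. No named gene had another probe set that names it alone, so that alternative gave no value. Leaving out the dimmest 30% ended the list calls of cell wall loosening in Col-0 (adjusted p = 0.107; 0.0264 to 0.107 over 10 alternatives) and lateral root initiation in the mutant (0.112; 0.0111 to 0.112), and auxin biosynthesis on IBA passed (0.0392; 0.0392 to 0.32).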

Other observations

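The 30 gene families defined by shared symbols were tested with camera after the data were seen, and none of the calls below held with an estimated correlation. Of 8 autophagy (ATG) genes 7 rose in Col-0 on IBA, among them ATG8B by 1.32 (SE 0.17), ATG8F by 1.04 (SE 0.10) and ATG8H by 0.72 (SE 0.09), with a family median of 0.55 (adjusted p = 2.67e-06, and 0.439 with an estimated correlation); 2 of 8 rose with spike scaling. In the mutant 3 of 8 rose, ATG8E by 0.59, ATG8H by 0.45 and ATG8F by 0.44 (adjusted p = 0.00505, and 0.611 with an estimated correlation). The response was lower in the mutant for ATG8B (-0.92), ATG8F (-0.60) and ATG8G (-0.46), with a family median that flips from -0.22 to 0.32 under spike scaling (0.011, and 0.519 with an estimated correlation). On DMSO ATG8F and ATG8H were higher in the mutant by 0.57 and 0.48 (1.55e-05, and 0.538 with an estimated correlation), calls that spike scaling ended. On IBA 1 of 8 was lower in the mutant and the family did not pass (median 0.009, camera adjusted p = 0.904). As deposited, the lower family response thus came with a higher family level on DMSO, while no family difference on IBA was called. A test that did not pass does not show equal levels on IBA. ATG8B, with the most negative difference of responses given here, was not among the genes called higher on DMSO. Neither the response call nor the DMSO call held with an estimated correlation.

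Of 47 UGT genes 11 rose and 4 fell in Col-0 on IBA (adjusted p = 0.0174, and 0.439 with an estimated correlation), a direction that flips with spike scaling (6 and 22, median -0.35). Of 8 RPS genes 3 fell in the mutant on IBA (0.0188, and 0.611 with an estimated correlation), calls that spike scaling ended (median -0.23 instead of -0.33). The response was higher in the mutant for 3 of 22 TBL genes (0.0315), 2 of 15 IQD genes (0.0427) and 2 of 11 PRA genes (0.0441), and for 18, 13 and 9 of them with spike scaling. It was lower for 1 of 8 ALDH genes (0.0441), a median that flips from -0.08 to 0.46 with spike scaling, and all 4 families are at 0.519 with an estimated correlation. On DMSO 1 of 9 XTH genes was lower in the mutant (0.0495, and 0.538 with an estimated correlation). On IBA 4 of 22 TBL and 4 of 15 IQD genes were higher (both 0.0336, and 0.729 with an estimated correlation), or 17 and 13 with spike scaling.

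Of the 8730 probe sets with no named gene 1396 rose and 979 fell with IBA in Col-0, and 633 and 369 in the mutant.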
